A study of Rattus norvegicus with 8 samples.

How the data were processed

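Uterine RNA from ovariectomized Sprague-Dawley rats was measured on 8 one-colour Agilent arrays of design 028279, 2 for each of 4 groups: control, estradiol, triclosan and zinc pyrithione. Groups and replicate numbers were taken from the sample labels. Per the labels, ovariectomy preceded dosing by 2 weeks, treatment lasted 3 days, uteri were taken 24 h after the last dose, and RNA needed an integrity number of at least 8. The labels give corn oil at 5 ml/kg for estradiol and triclosan, the latter subcutaneously, and injected corn oil alone for controls, and state no dose, route or vehicle for zinc pyrithione. Per the file headers, all 8 arrays lay on 1 slide, were scanned in 1 run and were read with Agilent Feature Extraction 11.5.1.1. Control and estradiol arrays occupied the first row of positions on the slide, and triclosan and zinc pyrithione arrays the second. Row and treatment were therefore confounded in each comparison of triclosan or zinc pyrithione with control or with estradiol. Estradiol against control and triclosan against zinc pyrithione each lay within 1 row but were confounded with column. Control and triclosan arrays occupied columns 1 and 2, and estradiol and zinc pyrithione arrays columns 3 and 4. The mean signal of negative controls was 30.3, 33.6, 37.5 and 39.1 across the first row and 26.4, 33.5, 37.7 and 39.9 across the second.

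The scanner files hold spot intensity on a linear scale, and per the file headers the processed signal is the intensity after the software's background subtraction. The authors' deposited value table holds log2 values. Set against the scanner files, it was the log2 of the median spot signal without background subtraction, quantile normalized over the arrays, with column medians of 7.40 to 7.41 and no centring of genes. Higher table values were brighter spots. In that table the 2 zinc pyrithione columns held each other's arrays (rank correlation 1.00000 with the other replicate's scanner file and 0.98388 with the file of the same label), which changes no comparison between groups. The table was used only as an alternative.

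Each array held 62976 spots, of which 58717 were not controls and represented 30367 probes. Processed signals were put on the log2 scale, the array's 75th percentile was subtracted, and spots of 1 probe were averaged without those marked as outliers, which removed 3 probe values. Probes were kept when at least 0.5 of their spots were well above background on both arrays of at least 1 group. Of the 30367 probes, 21804 were kept, and 18558 of them were well above background on all 8 arrays. Probe accessions, without versions, were matched to a gene table of the rat assembly GRCr8, used for names only: 18438 probes matched 1 symbol (15507 symbols), 0 matched several and 11929 matched none and kept the accession. Each gene was represented by its brightest probe over all 8 arrays, leaving 19167 genes and transcripts, 11969 with a symbol and 7198 without. Of the genes with kept probes, 2416 had more than 1, and opposite calls from probes of the same gene occurred for 48 genes in estradiol against control, 3 in triclosan against estradiol, 41 in zinc pyrithione against estradiol and 0 in the other comparisons. None of the genes named in the text was among them. No coordinates were used.

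All 8 arrays entered 1 linear model with 4 group means (limma 3.58.1, lmFit and eBayes, R 4.3.3), with 4 residual and 2.326 prior degrees of freedom. The replicate number was no block in this model. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Errors given with log2 fold changes are the standard errors (SE) of this model, with n = 2 arrays per group throughout, and folds without a log2 value are the same differences on the linear scale. Where no probe of a gene was well above background on either array of 1 compared group, but not so in the other, a bound is given. It is given as "at least N-fold", the mean of the brighter group against, per array, the higher of the gene's own signal and the lowest signal among probes well above background. A gene well above background on only 1 array of a group, or only by another of its probes, kept its fold. Such a fold can rest on signal near background. A total of 25 gene lists was tested with camera at a preset correlation of 0.01, adjusted over the lists of 1 comparison, and again with an estimated correlation. The lists covered estrogen-induced uterine genes, cell cycle, complement and antimicrobial proteins, extracellular matrix, smooth muscle, contraction, epithelium, stroma, endothelium, granulocytes and mast cells, macrophages and lymphocytes, adipocytes, ovary and oviduct, blood cells, xenobiotic metabolism, metallothioneins and zinc transport, heat shock proteins, NRF2 targets, endoplasmic reticulum chaperones, interferon response, steroid receptors, the insulin-like growth factor axis, sterol and fatty acid synthesis, calcium transport and immediate early genes. Counts given as adjusted over the list alone use only the list's measured members.

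Named genes followed a rule. In each comparison with control they were the 10 largest changes in each direction with both treated arrays beyond both controls and a gene symbol, up to 4 called members per list (or the member with the smallest p, as values only), and S100g, C3, Pgr, Esr1, Ltf, Igf1 and Mki67. Where under 10 genes passed, the 5 strongest in each direction were added as values, and comparisons between treated groups gave the 5 largest in each direction. Some were left out for length, the smallest changes first. Some genes chosen by this rule are not reported here. The exceptions are the transcript DV717163, Orm1, and the genes of stratified epithelium, hedgehog signalling, the clock and the first triclosan array that close the text, which were chosen after their values were seen. The groups, the test, the lists, the naming rule and most alternatives were fixed before the data were examined.

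Alternatives were normexp background correction (offset 50), quantile normalization, scaling to the median, no filter on dim probes, a filter on all 8 arrays, the authors' table, the mean of a gene's probes, every probe on its own, an intensity trend or robust variances in eBayes, only the groups compared, a replicate block, a 2-fold minimum, an estimated correlation, and leaving out each array in turn. Normexp was planned on the mean spot signal, which the files used here lack, so the median spot and median background signals were used. When an array is left out, the remaining one of its group is assumed to vary like the other groups, and the set of probes stays the same. Shared controls were treated with 100 simulated data sets of unchanged groups measured against the same simulated controls. Data were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

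The gene and list tests were tested on simulated data with the real means and spreads of 19167 genes, 200 of them changed by 2-, 4- or 8-fold. For estradiol against control, 20.9%, 83.6% and 97% of the changed genes were recovered at those folds, with 5 false calls among 146. For triclosan against control the shares were 38.8%, 86.6% and 97% with 10 false calls among 160, and for zinc pyrithione against control 35.8%, 85.1% and 95.5% with 11 false calls among 158. A list moved by 2-fold was called in each of these simulations and no other list was. The simulated genes varied independently of each other and with the same spread in every group. In the data, correlations estimated within lists reached 0.791 (smooth muscle). Triclosan replicates also differed with a standard deviation of 0.596, against 0.304 for controls. The simulated recovery, false calls and list calls therefore need not hold for the data. The number of arrays limits the precision: the median SE of a log2 fold change was 0.20.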

Results

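Gene expression in the uterus of ovariectomized rats was measured on 8 arrays, 2 each from animals given corn oil alone (control), estradiol, triclosan or zinc pyrithione. Removing the ovaries takes away the main source of estrogen, so that a response to an added compound stands against a low background. Estradiol is the main natural estrogen, triclosan is an antibacterial phenol of personal care products, and zinc pyrithione is an antimicrobial zinc complex. Per the labels, estradiol was given at 10 µg/kg/day. They list triclosan at 2, 10 and 50 mg/kg/day without saying which dose was arrayed, and give neither dose nor vehicle for zinc pyrithione. The 75th percentile of the signal was 1208 and 1271 on the control arrays, 768 and 838 on the estradiol arrays, 856 and 1293 on the triclosan arrays and 1420 and 1366 on the zinc pyrithione arrays. Between 70.0% and 76.1% of spots were well above background, and 0 were saturated. Replicates differed with a standard deviation of 0.304 (control), 0.309 (estradiol), 0.371 (zinc pyrithione) and 0.596 (triclosan) on the log2 scale, over probes well above background on all 8 arrays. On the triclosan arrays, 7.66% of those probes differed by more than 2-fold between replicates, against 1.11% on the control arrays. The labels do not say whether replicates are separate animals or pools, so p-values measure only the spread between these samples. Each SE pools the spread of all 4 groups, which is unequal, so it does not measure the spread of the compared groups alone. With only the compared groups fitted, estradiol against control gave 10354 genes in place of 8750. Triclosan against control gave 0 in place of 265. Triclosan and zinc pyrithione arrays lay in another row of the slide than control and estradiol arrays. Estradiol and zinc pyrithione arrays lay in other columns than control and triclosan arrays. Where compared groups differ in row or column, this position cannot be separated from treatment.

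Estradiol against control asks what an estrogen does in this tissue and gives the reference for the other treatments. In the estradiol uteri, Cuzd1, which encodes a CUB and zona pellucida-like domain protein, was 1840-fold higher (log2 10.84 ± 1.40, adjusted p = 0.0027). The antimicrobial lectin gene Reg3b was at least 886-fold higher (log2 10.42 ± 0.60, adjusted p = 0.00098). Genes of keratinizing epithelium were also among the largest increases. Ly6d rose at least 1100-fold (log2 10.53 ± 2.56), the keratin genes Krt16 at least 401-fold (9.79 ± 2.04) and Krt6c 775-fold (9.60 ± 2.58), and the cystatin gene Csta at least 539-fold (9.08 ± 1.94). Lipf, which encodes gastric lipase, rose 1100-fold (10.11 ± 1.89), Tprg1 at least 539-fold (9.07 ± 1.40), C20h6orf15 at least 437-fold (8.97 ± 1.41) and the metallothionein gene Mt4 499-fold (8.96 ± 1.45). In the other direction, the calcium pump gene Atp2b2 was at least 66.6-fold lower (log2 -6.69 ± 0.69, adjusted p = 0.0019). The thioesterase gene Them5 was 48.6-fold lower (-5.60 ± 0.77). Gulo, the last enzyme of vitamin C synthesis, was at least 43-fold lower (-5.43 ± 0.91), Gstm7 42.2-fold (-5.40 ± 1.04), the endocytic receptor Lrp2 40.1-fold (-5.33 ± 1.28) and Calca, the gene of calcitonin and its related peptide, at least 18.7-fold (-5.32 ± 0.67). Gnmt fell at least 21.6-fold (-5.23 ± 0.29), the phosphatase subunit gene Ppp2r2b 34.7-fold (-5.12 ± 0.55), the potassium channel gene Kcna2 at least 34-fold (-5.09 ± 0.69) and Ihh, the gene of a hedgehog signal, 31.6-fold (-4.98 ± 1.08). Adjusted p for all of these lay between 0.00092 and 0.025. The SE of these folds pools all 4 groups, so it does not measure the spread of control and estradiol arrays alone. With both triclosan arrays left out, 111 of the 112 called genes chosen by the naming rule stayed called. Leaving out 1 array ended some of the calls listed above. Those of Ly6d (adjusted p = 0.058 to 0.097) and Krt16 (0.052 to 0.06) ended without any single control or estradiol array, and that of Krt6c without Control 1 or either estradiol array (0.082 to 0.13). Csta and Lrp2 were lost without either control or Estradiol 1 (0.051 to 0.081), Ihh without either control or Estradiol 2 (0.057 to 0.069), Lipf without Control 1 (0.05) and Gstm7 without Estradiol 2 (0.051).

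Some known estrogen targets of the uterus rose strongly, while other genes listed with them fell or did not pass. S100g, the calcium-binding protein calbindin-D9k, was 21.6-fold higher (log2 4.43 ± 0.86, adjusted p = 0.009), complement component C3 154-fold (7.27 ± 1.51, adjusted p = 0.011), and lactotransferrin, Ltf, at least 13.9-fold (4.23 ± 0.50, adjusted p = 0.0023). The S100g call ended without Control 1 (adjusted p = 0.054), and that of C3 without Control 1 or either estradiol array (0.052 to 0.066). The progesterone receptor gene Pgr gave log2 0.42 ± 0.27 (adjusted p = 0.24), the estrogen receptor gene Esr1 -0.34 ± 0.15 (0.1), Igf1 -0.39 ± 0.30 (0.32) and the proliferation marker Mki67 0.65 ± 0.57 (0.37). Esr1 passed without either triclosan array (adjusted p = 0.04), and Igf1 with quantile normalization (0.0283) and in the authors' table (0.019), against a range of 0.019 to 0.43 over other settings and up to 0.68 without 1 array. Of the 27 estrogen-induced uterine genes measured, 14 rose, 5 fell and 8 did not pass, and adjusted over the list alone 15 rose and 6 fell. The connexin gene Gjb2 rose 67.7-fold (6.08 ± 0.67, adjusted p = 0.0021), while Ihh, a member of the list as fixed in advance, was among those that fell. The usual direction of each member under estrogen was not checked, so no conclusion is drawn from those that fell. The list shifted upward (median log2 1.07, camera adjusted p = 0.0307, adjusted p = 0.449 with an estimated correlation), which ended with normexp, without a filter on dim probes and with the filter on all 8 arrays (adjusted p up to 0.2). In the calcium transport list of 9, 4 rose and 3 fell, the same as adjusted over the list alone, with no shift of the list (median 0.08, adjusted p = 0.765). The channel gene Trpv6 was 3.36-fold higher (1.75 ± 0.26) and the calcium sensor gene Stim1 lower (-1.01 ± 0.15). Of 9 steroid receptors and coregulators, 2 rose and 4 fell, also when adjusted over the list alone: the glucocorticoid receptor gene Nr3c1 was 3.06-fold lower (-1.61 ± 0.13) and the orphan receptor gene Esrra higher (1.24 ± 0.16). Their median of -0.34 (adjusted p = 0.335) turned positive with normexp, as did the log2 of the membrane receptor gene Gper1, which was -2.27 ± 0.36 (at least 2.96-fold lower, adjusted p = 0.0047) and became 0.03 (adjusted p = 0.895, range over other settings 0.0019 to 0.9). In the insulin-like growth factor axis, 3 of 12 rose and 6 fell (7 adjusted over the list alone), with the binding protein gene Igfbp2 13.3-fold higher (3.74 ± 0.42) and Irs2 5.55-fold (-2.47 ± 0.32) and Igfbp3 (-1.96 ± 0.32) lower (median -0.76, adjusted p = 0.237).

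**Figure D1:**
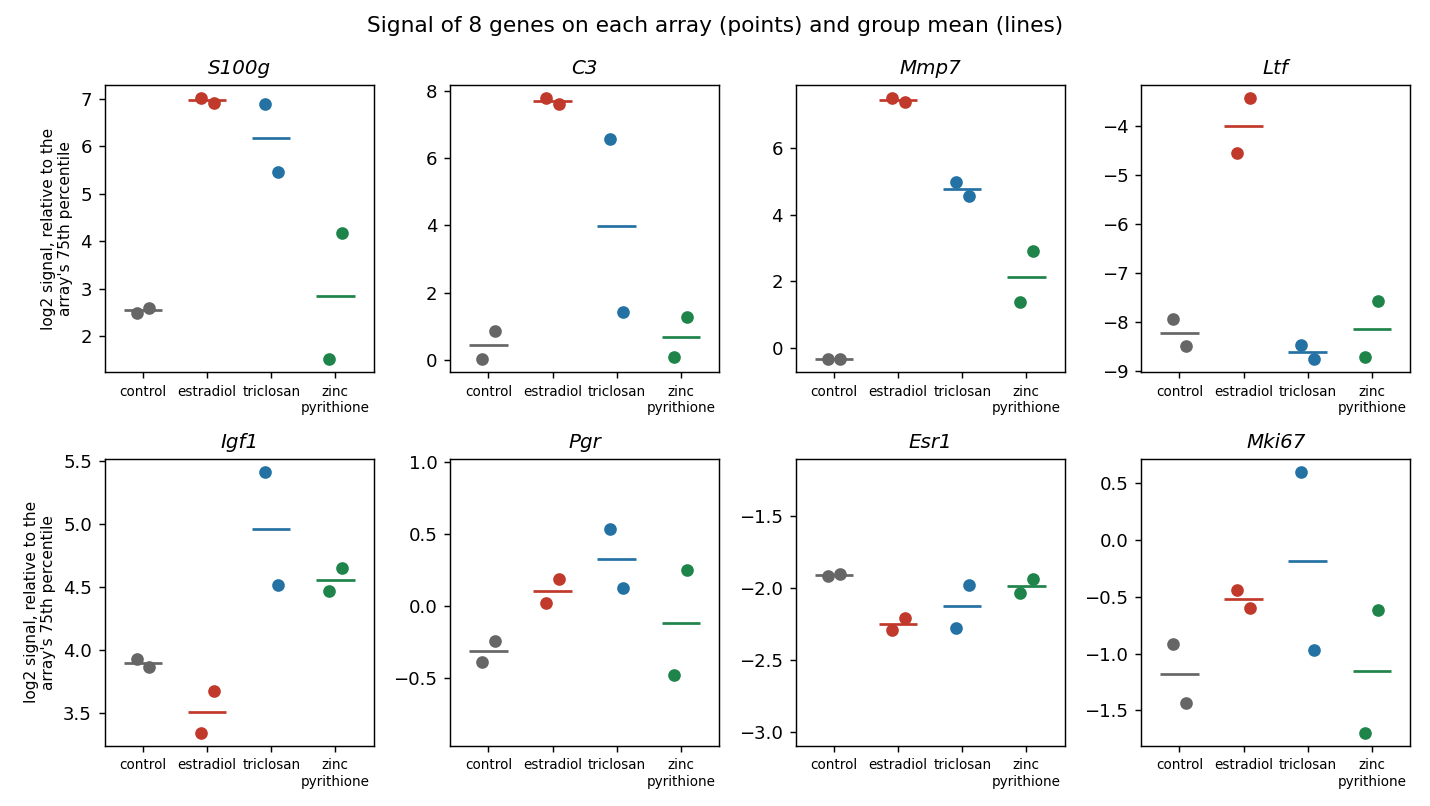
Signal of 8 genes on each array, as log2 relative to the array's 75th percentile (vertical axis), with a point per array and a line at each group's mean. S100g lay at 2.48 and 2.60 on the control arrays, 7.02 and 6.92 with estradiol, 6.89 and 5.45 with triclosan, and 1.51 and 4.17 with zinc pyrithione.

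Markers of tissue compartments moved in different directions under estradiol. Of 15 epithelial markers, 11 rose and 1 fell (12 and 1 adjusted over the list alone), among them the keratin genes Krt7 (16.5-fold, log2 4.05 ± 0.32), Krt19 (13.1-fold, 3.71 ± 0.30) and Krt8 (11-fold, 3.46 ± 0.36) and the membrane protein gene Prom1 (11.7-fold, 3.55 ± 0.38), and a list median of 1.47 (camera adjusted p = 0.000199). Of 11 stromal markers, 9 fell and 0 rose (10 fell adjusted over the list alone), with the transcription factor genes Tcf21 (5.97-fold lower, -2.58 ± 0.18), Twist2 (-1.90 ± 0.31) and Twist1 (-1.80 ± 0.22), and a median of -1.17 (adjusted p = 0.000849). Both calls were lost with an estimated correlation, at adjusted p = 0.303 for the epithelial and 0.3 for the stromal list. Endothelial markers had 6 of 11 lower (7 adjusted over the list alone), including the tight junction gene Cldn5 (5.15-fold lower, -2.37 ± 0.43) and Tie1 (-1.73 ± 0.27). Their median of -0.81 did not pass (adjusted p = 0.0531) and passed without either triclosan array (0.0459) or either zinc pyrithione array (0.0483), and with 5 of 9 other settings (lowest 0.0106). Smooth muscle markers showed no shift (median -0.17, adjusted p = 0.955): 2 of 13 rose and 2 fell (1 and 2 adjusted over the list alone), with the intermediate filament gene Des higher (1.35 ± 0.24). Among 12 contraction-associated genes, 3 rose and 3 fell, also adjusted over the list alone. The gap junction gene Gja1 was 4.82-fold higher (2.27 ± 0.23), and the prostaglandin receptor genes Ptgfr at least 7.88-fold (-3.45 ± 0.26) and Ptger3 at least 9.25-fold lower (-3.21 ± 0.56). The median of -0.41 (adjusted p = 0.509) turned positive with normexp. Of 18 extracellular matrix genes, 5 rose and 3 fell, also adjusted over the list alone, with the protease inhibitor gene Timp1 10.1-fold higher (3.33 ± 0.19) and the matricellular gene Tnc 5.18-fold higher (2.37 ± 0.50, ended without Control 2 or Estradiol 1, adjusted p = 0.059 to 0.067), with a median of 0.20 (adjusted p = 0.335). In the ovary and oviduct list of 7, 1 fell (0 adjusted over the list alone), the inhibin subunit gene Inha (-0.96 ± 0.28, adjusted p = 0.034), a call that ended without any single control, estradiol or zinc pyrithione array (0.058 to 0.14). The median of -0.29 (adjusted p = 0.762) turned positive with normexp. Adipocyte markers had 3 of 6 higher and 1 lower, also adjusted over the list alone: Adipoq, the gene of adiponectin, rose 51.8-fold (5.69 ± 0.54), Pck1 rose (1.91 ± 0.31) and the lipase gene Lpl fell (-1.68 ± 0.26). The list median was 1.33 (adjusted p = 0.335).

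Complement and antimicrobial genes were the immune list with the largest share of increases under estradiol. Of 18 complement and antimicrobial genes, 14 rose and 0 fell (15 rose adjusted over the list alone), with the protease inhibitor gene Slpi 48.1-fold (log2 5.59 ± 0.39) and complement factor B, Cfb, 18.1-fold higher (4.18 ± 0.73). The list median was 2.36 (camera adjusted p = 1.04e-05). Of 15 interferon response genes, 8 rose and 0 fell, also adjusted over the list alone, with Irf1 higher (1.72 ± 0.24, adjusted p = 0.0034) and the ubiquitin-like gene Isg15 6.49-fold higher (2.70 ± 0.69), the latter lost without any single control or estradiol array (adjusted p = 0.071 to 0.092). The median of that list was 0.95 (adjusted p = 0.00337). Granulocyte and mast cell markers had 6 of 11 higher (7 adjusted over the list alone), including the eotaxin receptor gene Ccr3 at least 12.4-fold (4.73 ± 0.44) and the stem cell factor receptor gene Kit (2.26 ± 0.31). The list median was 0.82 (adjusted p = 0.0129). These 3 lists had adjusted p = 0.3, 0.482 and 0.3 with an estimated correlation. Of 13 macrophage and lymphocyte markers, 3 rose and 1 fell, also adjusted over the list alone, with Cd68 3.15-fold (1.66 ± 0.28) and Aif1 (1.35 ± 0.21) higher and no shift of the list (median 0.21, adjusted p = 0.391). Blood cell genes had 3 of 7 lower, also adjusted over the list alone (median -0.38, adjusted p = 0.113). The hemoglobin genes Hbb-b1 (-1.21 ± 0.26, adjusted p = 0.012) and Hbb (-1.10 ± 0.24, adjusted p = 0.013) were among them, calls that ended without either control or Estradiol 2 (0.054 to 0.073).

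Biosynthetic and stress genes formed a further part of the estradiol response. Of 14 endoplasmic reticulum chaperones, 12 rose and 0 fell (13 rose adjusted over the list alone): Sdf2l1 6.39-fold (log2 2.67 ± 0.25), Dnajc3 3.61-fold (1.85 ± 0.19) and calreticulin, Calr, 3.41-fold (1.77 ± 0.15), with a median of 1.52 (camera adjusted p = 1.35e-06). Of 12 sterol and fatty acid synthesis genes, 8 rose, also adjusted over the list alone, with the isoprenoid pathway genes Idi1 11.7-fold (3.55 ± 0.35) and Fdps 5.95-fold (2.57 ± 0.21) higher. The median of the list was 1.5 (adjusted p = 0.000703). NRF2 targets had 6 of 11 higher and 1 lower, also adjusted over the list alone, with the cystine transporter gene Slc7a11 9.52-fold (3.25 ± 0.27) and the sulfiredoxin gene Srxn1 8.07-fold (3.01 ± 0.31) higher (median 1.14, adjusted p = 0.0129). With an estimated correlation the adjusted p of these 3 lists was 0.3, 0.303 and 0.3. Of 23 cell cycle genes, 4 rose (2 adjusted over the list alone), with the cyclin gene Ccne1 10.4-fold (3.38 ± 0.67) and Cdk1 7.91-fold (2.98 ± 0.63) higher, both ended without either control or Estradiol 1 (adjusted p = 0.052 to 0.062). That list's median was 0.76 (adjusted p = 0.0268, adjusted p = 0.601 with an estimated correlation), and its call ended without Control 2 (0.0524), without Estradiol 1 (0.0895), with normexp and without a filter on dim probes (up to 0.153). Of 8 heat shock genes 3 rose, also adjusted over the list alone, with Hspa8 at 0.75 ± 0.19 (adjusted p = 0.019), which ended without either control or Estradiol 1 (0.081 to 0.1). Their median of 0.43 (adjusted p = 0.102) passed without Estradiol 2 (0.0457). Xenobiotic metabolism genes had 2 of 11 higher and 7 lower (8 lower adjusted over the list alone), with Gstm1 8.91-fold (-3.15 ± 0.55) and Aldh1a1 6.98-fold (-2.80 ± 0.27) lower. Their median of -1.38 (adjusted p = 0.0761) passed without Control 1 (0.0492) or either triclosan array (0.0459), and with 3 of 9 other settings (lowest 0.022). Metallothioneins and zinc transporters had 1 of 10 higher and 6 lower (1 and 7 adjusted over the list alone): the zinc transporter gene Slc30a2 was 11.4-fold (-3.51 ± 0.24), Mt2A 9.47-fold (-3.24 ± 0.44) and Mt1 5.97-fold lower (-2.58 ± 0.38). The median of -1.12 (adjusted p = 0.0531) passed without Control 1, Estradiol 2, either triclosan array or either zinc pyrithione array (0.0386 to 0.049), and with 5 of 9 other settings (lowest 0.0182). Of 14 immediate early genes, 5 rose and 1 fell, also adjusted over the list alone, with Fos 10.4-fold higher (3.38 ± 0.79, ended without Control 1 or either estradiol array, 0.053 to 0.094) and a list median of 0.75 (adjusted p = 0.0807, passing without Control 2 at 0.0462 and with the filter on all 8 arrays at 0.0448).

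Across all 19167 genes and transcripts tested with limma, 8750 (45.7%) differed between estradiol and control, 4143 higher and 4607 lower, and 4845 of them by at least 2-fold. Of the 8750, 15 were well above background in neither group. The median log2 fold change of all genes was -0.07 and moved to 0.18 with normexp and 0.19 without a filter on dim probes, against which list medians have to be read. The higher calls were 47.3% of all calls and became 62.7% with normexp (5712 against 3394) and 62.1% without the filter (7230 against 4417). The count was 3869 without Control 1, 4741 without Control 2, 4622 without Estradiol 1 and 4470 without Estradiol 2.

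Triclosan against control asks whether triclosan changes uterine genes, and whether they are those of an estrogen. Mmp7, which encodes the secreted protease matrilysin, was 34.6-fold higher (log2 5.11 ± 0.46, adjusted p = 0.033), at 4.99 and 4.57 on the triclosan arrays, -0.34 and -0.33 on the control arrays and 7.51 and 7.38 on the estradiol arrays. Reg3b rose at least 12.5-fold (4.27 ± 0.60), the neurotrophin receptor gene Ngfr 18.7-fold (4.22 ± 0.51), the prostaglandin D synthase gene Hpgds at least 10.4-fold (3.80 ± 0.44), the trefoil factor gene Tff2 at least 5.08-fold (3.24 ± 0.37) and the asparaginase gene Aspg 8.96-fold (3.16 ± 0.49). Further increases were in Cd5l (at least 3.73-fold, 2.94 ± 0.43), the neurofilament gene Nefh (at least 4.19-fold, 2.90 ± 0.44), the addressin gene Madcam1 (at least 5.9-fold, 2.80 ± 0.35) and Bcat1, the gene of a branched-chain aminotransferase (6.84-fold, 2.77 ± 0.18). The neurexophilin gene Nxph1 fell at least 8.76-fold (-4.28 ± 0.42), the glutamate receptor gene Grm7 at least 4.87-fold (-2.94 ± 0.40), the ferroxidase-like gene Hephl1 at least 4.8-fold (-2.67 ± 0.17), and the prostaglandin F receptor gene Ptgfr 6.37-fold (-2.67 ± 0.26). Lower too were Tmem116 (at least 5.72-fold, -2.52 ± 0.24), the phosphodiesterase gene Pde1c (at least 4.67-fold, -2.40 ± 0.27), the chemokine gene Ccl25 (at least 2.82-fold, -2.29 ± 0.31), the potassium channel subunit gene Kcne2 (4.86-fold, -2.28 ± 0.27), Dlg5l (at least 3.57-fold, -2.24 ± 0.21) and Pbld1 (4.7-fold, -2.23 ± 0.33). Adjusted p for these genes lay between 0.018 and 0.048. Each of these calls ended without Control 1 and without Triclosan 1, most also without Control 2 or an array of the other groups, and none without Triclosan 2 (adjusted p = 0.055 to 0.25 where a call ended). They also ended when only the control and triclosan arrays were fitted, and most of them without a filter on dim probes (adjusted p up to 0.65 over the alternatives).

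Among the estrogen targets fixed in advance, none passed in the triclosan uteri. S100g gave log2 3.64 ± 0.86 (12.4-fold, adjusted p = 0.068), C3 3.56 ± 1.51 (0.2), Igf1 1.07 ± 0.30 (0.093), Mki67 0.99 ± 0.57 (0.31), Pgr 0.65 ± 0.27 (0.19) and Esr1 -0.22 ± 0.15 (0.38), and Ltf was not well above background in either group. The 2 triclosan arrays differed: C3 lay at 6.58 on the first and 1.41 on the second, with the controls at 0.02 and 0.85. Without Triclosan 2, S100g, C3, Igf1 and Mki67 passed, but that fit holds 1 triclosan array and takes its spread from the other groups. Triclosan replicates differed more than those of any other group, so these passes do not measure the spread with triclosan. The same limit holds for every other pass without Triclosan 2. Over other settings with all arrays the adjusted p of S100g ranged from 0.036 to 0.2. Of the 27 estrogen-induced uterine genes, 0 passed in limma at an adjusted p under 0.05, and 10 higher and 1 lower did at the unadjusted level of 0.05. Adjusted over the list alone, 9 were higher. The list as a whole shifted upward (median 0.64, camera adjusted p = 0.00331, adjusted p = 0.401 with an estimated correlation), with medians of 0.85 and 0.48 on the 2 arrays. The lipocalin gene Lcn2 in it gave 2.70 ± 0.57 (adjusted p = 0.058, passing without Triclosan 2 at 0.018).

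Chaperone and sterol genes were the groups with the most called members. Of 14 endoplasmic reticulum chaperones, 8 rose and 0 fell (12 rose adjusted over the list alone), including Sdf2l1 (4.6-fold, log2 2.20 ± 0.25), Pdia4 (3.46-fold, 1.79 ± 0.17), Hspa5, the gene of BiP (3.18-fold, 1.67 ± 0.24), and Hyou1 (3.13-fold, 1.65 ± 0.22). The list median was 1.17 (camera adjusted p = 2.3e-09). Of 12 sterol and fatty acid synthesis genes, 3 rose (9 adjusted over the list alone), namely the epoxidase gene Sqle (4.04-fold, 2.01 ± 0.16), Fdps (3.36-fold, 1.75 ± 0.21) and Hmgcs1 (3.31-fold, 1.73 ± 0.25). Their list had a median of 1.44 (adjusted p = 1.11e-07). The adjusted p of each of these lists was 0.38 with an estimated correlation. The call of each of these 7 genes ended when any single array other than Triclosan 2 was left out (adjusted p = 0.055 to 0.25). Slc7a11 was the 1 NRF2 target of 11 to rise (3.91-fold, 1.97 ± 0.27, 4 higher adjusted over the list alone), Timp1 the 1 extracellular matrix gene of 18 (2.72-fold, 1.44 ± 0.19, 1 higher and 1 lower adjusted over the list alone), and the mast cell chymase gene Cma1 the 1 granulocyte and mast cell marker of 11 to fall (3.02-fold, -1.59 ± 0.26, 1 higher and 2 lower adjusted over the list alone). These 3 calls ended in the same way (0.073 to 0.25).

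Apart from Ptgfr, the 1 contraction gene of 12 to fall (2 higher and 2 lower adjusted over the list alone), no member of the remaining lists passed under triclosan, while some of those lists shifted. The cell cycle list of 23, in which no gene passed, shifted upward (median 0.93, camera adjusted p = 3.33e-05, 0 adjusted over the list alone), with medians of 1.39 and 0.43 on the 2 arrays, and the list of 8 heat shock genes shifted as well (median 0.76, adjusted p = 0.000135, 7 higher adjusted over the list alone), with the mitochondrial chaperonin gene Hspe1 at 0.81 ± 0.14. The list of 7 blood cell genes shifted downward (median -0.66, adjusted p = 0.00918, 3 lower adjusted over the list alone), with Hbb at -0.95, a call that ended without Triclosan 2 (0.0977). NRF2 targets shifted upward (median 0.45, adjusted p = 0.0223), also ended without Triclosan 2 (0.0727). The extracellular matrix list (median 0.42, adjusted p = 0.0469) ended without Control 2 (0.2), either estradiol array (0.0528) or Triclosan 1 (0.581) and under most other settings (up to 0.112), and its medians on the 2 arrays were 0.96 and 0.08. With an estimated correlation the adjusted p of these 5 lists was 0.727, 0.397, 0.476, 0.38 and 0.781. The other 17 lists did not shift (adjusted p = 0.0849 to 0.975). Of these, 3 passed without 1 array: smooth muscle (0.00216) and interferon response (0.0201) without Triclosan 2, and stroma (0.0446) without Control 2. With normexp stroma (0.0298) and xenobiotic metabolism (0.0482) passed, and without a filter on dim probes stroma. For 3 lists the signs differed between the median and the mean or the test: granulocytes (median 0.27, mean -0.03, upward test), contraction (0.07, -0.13, downward) and calcium transport (-0.02, 0.25, downward). Single members included Oxtr, the oxytocin receptor gene, at 1.58 ± 0.32 (adjusted p = 0.055), Krt19 at 1.37 ± 0.30 (0.062) and Aldh1a1 at -1.56 ± 0.27 (0.052), which passed without Triclosan 2 (0.01, 0.012 and 0.013).

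In total, 265 genes and transcripts (1.38%) differed between triclosan and control, 149 higher and 116 lower, and 5145 passed at the unadjusted level of 0.05. With scaling to the median, 657 passed and 67.1% were higher (441 against 216), compared with 56.2%. The count rested on single arrays: it was 5069 without Triclosan 2 and 5 without Triclosan 1, 1 without Control 1, 3 without Control 2, 2 without either estradiol array and 8 without either zinc pyrithione array. Other settings gave 0 (only these groups fitted, 3526 at the unadjusted level) to 1534.

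**Figure D2:**
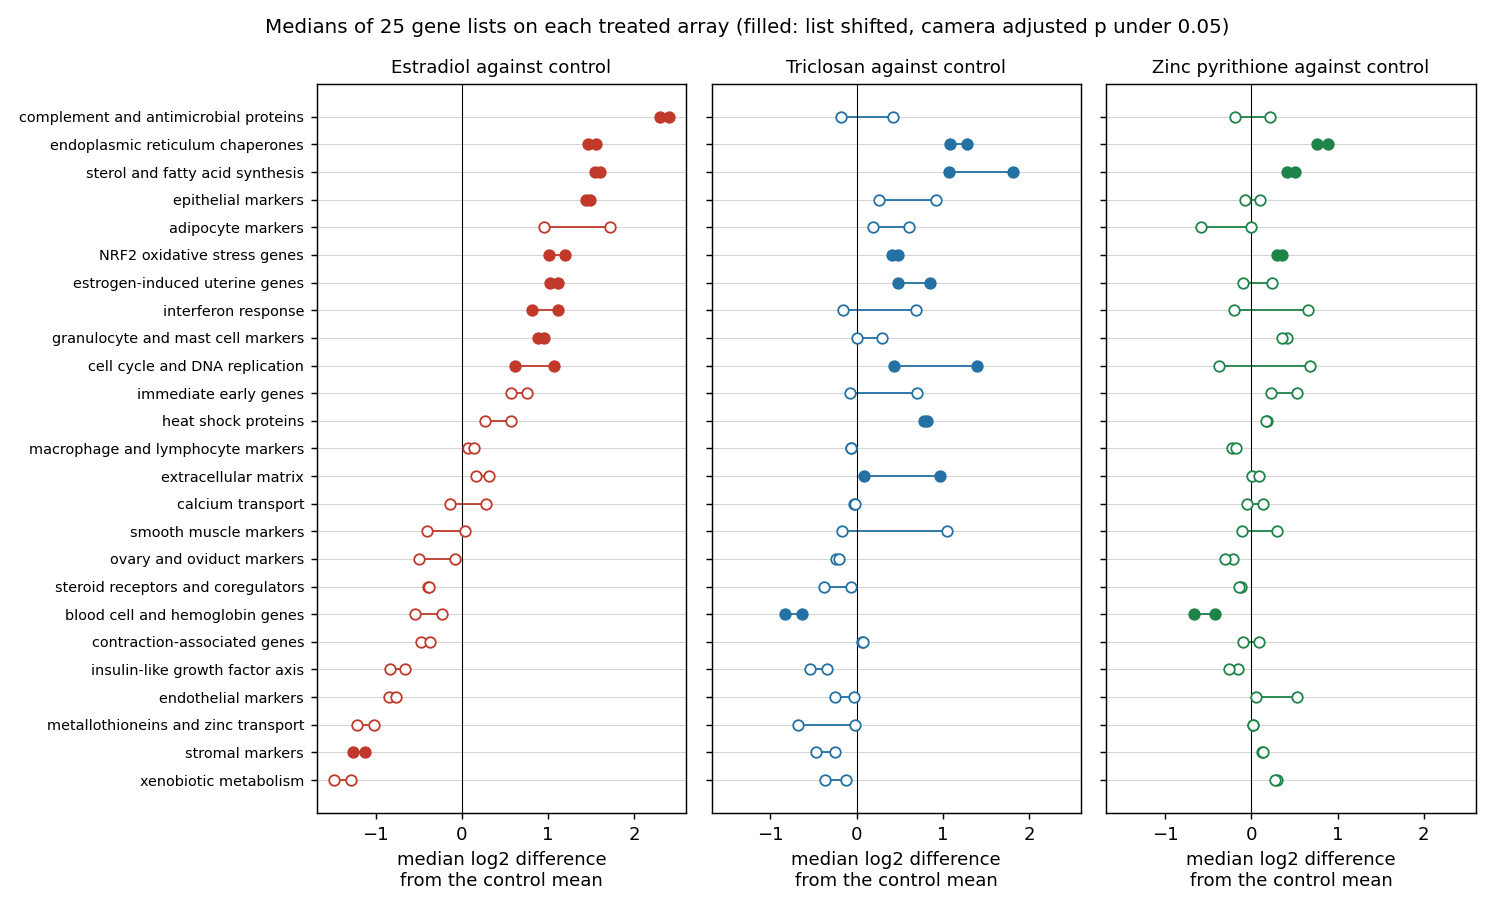
Median log2 difference from the control mean (horizontal axis) of the 25 gene lists on each treated array, in 1 panel per treatment, with filled points for lists with a camera adjusted p under 0.05 in that comparison. Endoplasmic reticulum chaperones lay at 1.28 and 1.09 on the triclosan arrays, and with another scaling or background correction the median of all arrays changed sign for contraction, steroid receptors, ovary and oviduct with estradiol, for calcium transport, endothelium, macrophages, ovary and oviduct with triclosan, and for cell cycle, complement, contraction and metallothioneins with zinc pyrithione.

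Zinc pyrithione against control asks what a second antimicrobial compound does in the same tissue. Spns3, which encodes a spinster family transporter, was 10.4-fold higher (log2 3.37 ± 0.24, adjusted p = 0.018), the neurotrophic factor receptor gene Gfra4 10.3-fold (3.37 ± 0.23, adjusted p = 0.015), Golt1a at least 4.43-fold (3.02 ± 0.18, adjusted p = 0.014) and the circadian repressor gene Ciart at least 4.43-fold (2.15 ± 0.14, adjusted p = 0.015). Hephl1 was at least 5.64-fold lower (-2.63 ± 0.17, adjusted p = 0.015), and it was also called lower with triclosan and with estradiol. Hephl1 lay at -5.37 and -5.38 on the control arrays and between -8.08 and -7.32 on every treated array. A fall with treatment and controls standing apart cannot be told apart here. The only other call was the unnamed transcript DV717163 (2.49 ± 0.14, adjusted p = 0.014), named here after its value was seen. These 6 were the only calls in limma, 5 higher and 1 lower, with 2773 at the unadjusted level of 0.05. The calls of the 5 genes with a symbol ended without any single control, estradiol or zinc pyrithione array (adjusted p = 0.061 to 0.21). With normexp the calls of Gfra4, Golt1a, Ciart and Hephl1 ended, in the authors' table and with an intensity trend those of Golt1a, Ciart and Hephl1, with only these groups fitted those of Spns3, Gfra4 and Ciart, and with quantile normalization that of Hephl1 (adjusted p up to 0.48 over these settings). The share of higher calls was 83.3%, compared with 100% with quantile normalization (5 against 0) and 58.6% with normexp (17 against 12). The count was 0 without Control 1, either estradiol array or either zinc pyrithione array (1395, 2220, 1843 and 1643 at the unadjusted level), 1 without Control 2 and 10 without either triclosan array.

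Among the genes next in rank, the carnosinase gene Cndp1 gave log2 2.58 ± 0.23 (adjusted p = 0.057), Igsf10 -1.13 ± 0.12 (0.12), the glutamate receptor gene Grin3a -3.51 ± 0.42 (0.12), Sema3d -1.86 ± 0.24 (0.12) and Ndst4 -1.07 ± 0.14 (0.13). None of the estrogen targets passed: S100g gave 0.31 ± 0.86 (adjusted p = 0.91), with 1 array below and 1 above the controls, C3 0.25 ± 1.51 (0.96), Pgr 0.20 (0.8), Esr1 -0.08 (0.87), Igf1 0.66 (0.38) and Mki67 0.02 (0.99), with Ltf not well above background in either group. No member of any list passed. Of the 14 endoplasmic reticulum chaperones, 11 were higher when adjusted over the list alone, with Calr at 0.94 ± 0.15 (1.92-fold, adjusted p = 0.13), and the list shifted upward (median 0.86, camera adjusted p = 3.82e-10). Sterol and fatty acid synthesis genes also shifted upward (median 0.46, adjusted p = 0.0112, 2 higher adjusted over the list alone), with Sqle at 0.84 ± 0.16. So did NRF2 targets (median 0.38, adjusted p = 0.0208, 0 adjusted over the list alone), with Slc7a11 at 0.85. Blood cell genes shifted downward (median -0.45, adjusted p = 0.00609, 2 lower adjusted over the list alone), with Hbb at -1.12 ± 0.24. With an estimated correlation these 4 lists had adjusted p = 0.462, 0.57, 0.462 and 0.57. The sterol call ended without Control 1 (0.123), and the NRF2 call without Zinc pyrithione 2 (0.0808). The metallothionein and zinc transport list, which holds known targets of zinc, did not shift (median -0.00017, mean 0.25, upward test, adjusted p = 0.329), with Slc39a4, an intestinal zinc importer gene, at 0.92 ± 0.13 (0.13). The other 20 lists did not shift either (adjusted p = 0.0503 to 0.831), and the signs of median, mean or test differed for cell cycle (-0.02, 0.16, upward), macrophages (-0.24, 0.01, downward) and stroma (-0.04, 0.08, upward). Of these lists, 7 passed without 1 array. Without Zinc pyrithione 1, these were interferon response (0.000266) and cell cycle (1.59e-06), without Zinc pyrithione 2 smooth muscle (0.0406), and without Control 2 granulocytes (0.0467). Heat shock proteins passed without Control 2 or Zinc pyrithione 2 (0.0406 to 0.0467), endothelium without either triclosan array or Zinc pyrithione 2 (0.00842 to 0.0456), and immediate early genes without Control 2, Zinc pyrithione 1 or any estradiol or triclosan array (0.00044 to 0.0456). With other settings immediate early genes (3 of 9, lowest 0.0258), endothelium (2 of 9, lowest 0.0198) and heat shock proteins (1 of 9, 0.0375) passed.

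Comparisons of the chemicals with estradiol ask directly how the responses differ. The hedgehog transcription factor gene Gli1 was 22.4-fold higher with triclosan than with estradiol (log2 4.49 ± 0.53, adjusted p = 0.0069), Calca at least 27-fold (5.85 ± 0.67) and Ppp2r2b 24.7-fold (4.63 ± 0.55). Among the largest decreases with triclosan relative to estradiol were the prolactin-induced protein gene Pip at least 47.7-fold (-6.50 ± 0.76, adjusted p = 0.0069), the kappa-casein gene Csn3 at least 58.8-fold (-6.35 ± 0.29, adjusted p = 0.0015), Zp3r at least 58.8-fold (-6.44 ± 0.21, adjusted p = 0.00082), Olfm4 at least 173-fold (-8.32 ± 1.28) and Lipf 640-fold (-9.32 ± 1.89). Atp2b2 (at least 14-fold, 4.44 ± 0.69) and the phosphatase gene Ptprq (21.3-fold, 4.41 ± 0.73) were higher. The calls of Calca, Ppp2r2b and Gli1 ended without Estradiol 2 (adjusted p = 0.05 to 0.052), those of Atp2b2, Ptprq and Olfm4 without either estradiol array (0.051 to 0.085), and that of Lipf without any single control or estradiol array (0.051 to 0.12). Together 4023 genes differed between triclosan and estradiol, 1881 higher and 2142 lower with triclosan (46.8% higher, against 34.6% without a filter on dim probes, 1500 against 2830). The count was 813 without Estradiol 1, 318 without Estradiol 2, 6840 without Triclosan 1, 2126 without either control and 2603 without either zinc pyrithione array. Only these 2 groups in the fit gave 37. The median log2 fold change of all genes moved from 0.05 to -0.11 with normexp and -0.12 without the filter.

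Zinc pyrithione and estradiol uteri differed in 7853 genes, 3914 higher and 3939 lower with zinc pyrithione. Calca was at least 411-fold (log2 9.77 ± 0.67, adjusted p = 0.0013), Atp2b2 at least 88.1-fold (7.09 ± 0.69), Gulo at least 83.4-fold (6.38 ± 0.91) and Gnmt at least 42.2-fold higher (adjusted p = 0.00085) with zinc pyrithione. The acute phase gene Orm1 was 78-fold higher (6.28 ± 1.38, adjusted p = 0.015), which ended without any single estradiol or zinc pyrithione array (0.061 to 0.068). Lipf was at least 7220-fold (-13.34 ± 1.89, adjusted p = 0.0047), Reg3b at least 1360-fold (-11.15 ± 0.60), its paralog Reg3g at least 490-fold (-9.04 ± 0.64), Mt4 495-fold (-8.95 ± 1.45) and Cuzd1 373-fold lower (-8.54 ± 1.40). The share of higher calls was 49.8%, 29.2% with normexp (2852 against 6911) and 36.8% without a filter (3696 against 6352), while the median log2 fold change of all genes moved from 0.01 to -0.24 and -0.22. The count was 3650 without Estradiol 1, 3530 without Estradiol 2, 2989 without Zinc pyrithione 1 and 4767 without Zinc pyrithione 2.

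Triclosan and zinc pyrithione, whose doses are not matched in the labels, differed in 13 genes, 3 higher and 10 lower with triclosan, with 3414 at the unadjusted level of 0.05. Bcat1 was 4.05-fold (log2 2.02 ± 0.18, adjusted p = 0.034) and the endoplasmic reticulum protein gene Erp27 3.98-fold higher (1.99 ± 0.17, adjusted p = 0.033) with triclosan. Lower with triclosan were the ATP-gated channel gene P2rx2 (40.7-fold, -5.35 ± 0.46), Spns3 (11.9-fold, -3.58 ± 0.24), Gfra4 (at least 11.2-fold, -3.48 ± 0.23), Lrcol1 (at least 6.6-fold, -3.05 ± 0.25) and Cndp1 (7.95-fold, -2.99 ± 0.23). Each of these 7 calls ended without either control and without either zinc pyrithione array, 6 of the 7 without Triclosan 1, and Bcat1, Erp27 and Cndp1 without either estradiol array (adjusted p = 0.058 to 0.27 where a call ended). The share of higher calls was 23.1% and 34.8% with normexp (16 against 30), which moved the median of all genes from 0.03 to 0.14. The count was 3197 without Triclosan 2, 8 without Triclosan 1, 5 without either control, 6 without either estradiol array, and 2 and 1 without Zinc pyrithione 1 and 2.

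How far the chemical responses resemble that to estradiol was measured by the covariance of log2 fold changes across the 19167 genes, which are not independent replicates. For estradiol and triclosan it was 0.605, against 0.0478 (highest 0.0525) in 100 simulations of unchanged groups sharing the controls, a difference of 0.557. The correlation was 0.744 (simulated 0.499), and 77% of genes had the same sign (simulated 66.7%). Of the 149 genes higher with triclosan, 124 were also higher with estradiol (32.2 for independent lists), and of the 116 lower 104 were also lower (27.9), while 6 were called in opposite directions. At the unadjusted level 3907 genes passed in both in the same direction, against a mean of 244 and at most 303 in the simulations. Reg3b, for example, gave log2 10.42 with estradiol and 4.27 with triclosan, and the chaperone gene Sdf2l1 2.67 and 2.20. For estradiol and zinc pyrithione the covariance was 0.187 (simulated 0.0478, difference 0.139), the correlation 0.337 (simulated 0.5) and the same-sign share 62.9%, with 1 gene called higher in both, Golt1a (1.08 for independent lists), which was not well above background with estradiol or in the controls, 1 lower in both, Hephl1 (0.24), 3 opposite, and 1548 at the unadjusted level (simulated 246). For triclosan and zinc pyrithione it was 0.160 (simulated 0.0477, difference 0.113), with a correlation of 0.529 (simulated 0.498), a same-sign share of 69.2%, 1 gene higher in both, Ciart (0.0389), 1 lower in both, Hephl1 (0.00605), 1 opposite, DV717163, and 1529 at the unadjusted level (simulated 243). Part of the excess may come from the shared controls, which cannot be split into sets of at least 2 arrays. Estradiol and zinc pyrithione arrays also shared columns, and triclosan and zinc pyrithione arrays a row, that the controls did not occupy. An effect of slide position could add to the covariance of these pairs. The simulations hold no such effect, and it was not tested. The simulations left every group unchanged, while 10553 of 19167 genes passed for estradiol and 5145 for triclosan at the unadjusted level. They therefore do not give the correlation, same-sign share or overlap of unrelated responses of such size. No conclusion is drawn from setting these 3 measures against the simulations. Leaving out Triclosan 2 or Triclosan 1 moved the estradiol and triclosan covariance to 0.869 or 0.341, and without Zinc pyrithione 2 that of estradiol and zinc pyrithione was 0.0983. Positions were taken along 8749 of the 8750 genes called for estradiol, those with a value on every array. With the controls at 0 and the estradiol group at 1, the first triclosan array lay at 0.559 and the second at 0.234. The zinc pyrithione arrays lay at 0.0659 and 0.178. These genes were called against the same controls. With different control arrays as references for the treated array and for estradiol, the triclosan arrays lay at 0.544 and 0.222. The zinc pyrithione arrays then lay at 0.0557 and 0.166. Each control array measured from the other lay at -0.0208 and 0.0587, so the first zinc pyrithione array is not told apart from the controls.

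**Figure D3:**
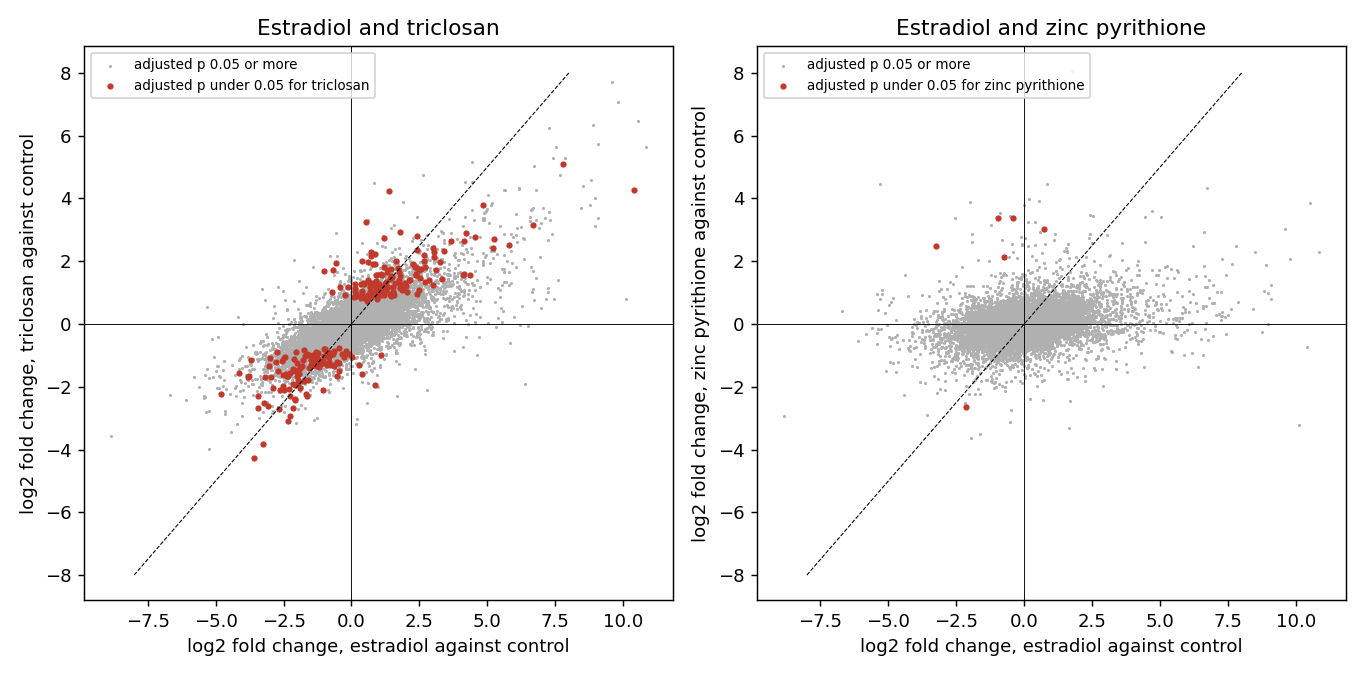
Log2 fold change against control of each gene with estradiol (horizontal axis) and with triclosan or zinc pyrithione (vertical axis, 1 panel each), with red points for genes at an adjusted p under 0.05 for that chemical and a dashed line of equal change. The correlation over all genes was 0.744 for triclosan and 0.337 for zinc pyrithione, where unchanged groups sharing the controls would give 0.499 and 0.5. These simulated values leave estradiol unchanged too, so they are no reference for a chemical unrelated to a strong estradiol response.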

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

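Of the alternatives below, leaving out the triclosan arrays, the crossed replicate block and separate control arrays were chosen only after results were seen. The triclosan and zinc pyrithione counts depended on the settings, and the cause was not tested. In place of 265 genes, triclosan against control gave 1343 with normexp, 891 with quantile normalization, 657 with scaling to the median, 1256 with a filter on all 8 arrays, 1534 in the authors' table and 1460 with an intensity trend. It gave 3 without a filter on dim probes and 0 with only these groups fitted (3526 at the unadjusted level in limma). Zinc pyrithione against control, 6 genes, gave 29 with normexp, 45 in the authors' table, 11 with the mean of a gene's probes, 10 without the triclosan arrays and 0 with the filter on all 8 arrays (2651 at the unadjusted level). Triclosan against zinc pyrithione, 13 genes, gave 46 with normexp, 34 in the authors' table, 27 with a trend, 4 without the dim filter, 3 with the filter on all 8 arrays and 1 with only these groups. Triclosan against estradiol gave 37 with only these groups. A 2-fold minimum, which can only lower counts, left 4845 genes for estradiol, 2096 for triclosan against estradiol and 4417 for zinc pyrithione against estradiol. With an estimated correlation 0 lists passed in each comparison with control, and with normexp 7 lists passed for zinc pyrithione. With normexp and in the authors' table the covariances fell to 0.279 and 0.300 for estradiol and triclosan, 0.0872 and 0.103 for estradiol and zinc pyrithione, and 0.0772 and 0.0855 for triclosan and zinc pyrithione. With each treatment set against a different control array the covariances were 0.571 for estradiol and triclosan, 0.153 for estradiol and zinc pyrithione, and 0.126 for triclosan and zinc pyrithione. Gper1, lower with estradiol, turned to log2 0.0298 with normexp. Leaving out 1 array gave 3869 to 10514 genes for estradiol, 1 to 5069 for triclosan, 0 to 10 for zinc pyrithione (3 to 7 lists), 318 to 6840 for triclosan against estradiol, 2989 to 9844 for zinc pyrithione against estradiol and 1 to 3197 for triclosan against zinc pyrithione, and a covariance of 0.116 to 0.227 for triclosan and zinc pyrithione. Genes under background give only bounds on a fold, so the ranking of the largest changes is limited by signal.

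Replicate numbers showed little pairing between most groups. Deviations of the first replicates from their group means correlated by 0.0331 to 0.0505 between control, estradiol and triclosan. The values were 0.0152 and -0.0748 between zinc pyrithione and the control and estradiol groups. Between triclosan and zinc pyrithione it was -0.252, which leaves a structure shared by these groups open. Its sign rests on the order of the zinc pyrithione replicates, which differs between the scanner files and the authors' table. With a replicate block, 1 gene passed for triclosan (4741 at the unadjusted level) and 3 for triclosan against zinc pyrithione. For zinc pyrithione 4 passed, 3 of them among the 6, and the calls of Spns3, Ciart and Hephl1 ended. The triclosan smooth muscle list passed with the block (0.018). With the zinc pyrithione replicates crossed, 3 genes passed for triclosan against zinc pyrithione.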

Other observations

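The gene groups of this paragraph and the next and all tests of artifacts below except that of array brightness were chosen only after the result was seen, so their counts do not test whether a group changed. Many genes of stratified epithelium, the kind that lines the vagina and skin, rose with estradiol. Of 19 such genes, 16 rose and 0 fell, compared with 4143 higher among all 19167, but only 6 of the 16 calls held without any single array. Those that held included Krt13 (32.5-fold, log2 5.02 ± 0.83, adjusted p = 0.0056), Krt1 (19.2-fold, 4.26 ± 0.75), the serpin gene Serpinb5 (15.3-fold, 3.94 ± 0.55) and the desmosomal cadherin gene Dsg3 (10-fold, 3.32 ± 0.54). The 10 that ended were Ly6d, Krt16, Krt6c and Csta, the basal keratin genes Krt14 (36.3-fold, 5.18 ± 1.03, ended without Control 1 or Estradiol 1, 0.054 to 0.062) and Krt5, Krt17, Sprr1a, Cnfn and Tgm3. With triclosan, 0 of the 19 passed, with Krt13 at 4.12 ± 0.83 (adjusted p = 0.055) and Dsg3 at 2.41 ± 0.54 (0.063), which passed without Triclosan 2 (0.034 and 0.014). In some other settings with all 8 arrays, Krt13 (adjusted p = 0.026 to 0.038), Krt5 (0.035 to 0.046), Sprr1a (0.042 and 0.049), Dsg3 (0.043) and Krt14 (under 0.05) passed with triclosan. With zinc pyrithione 0 passed, with Krt13 at 3.42 ± 0.83 (0.19).

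Hedgehog signalling carries signals from epithelium to stroma in the uterus, and 6 of 7 of its genes were lower with estradiol, as were 9 of 11 stromal markers. Only 3 of the 6 calls held without any single array. The transcription factor gene Gli1 was 29.8-fold lower (log2 -4.90 ± 0.53, adjusted p = 0.0021) and the signal transducer gene Smo 4.7-fold (-2.23 ± 0.21, adjusted p = 0.0017), while Gli3 held without any array and ended with normexp (0.86). The calls of Ihh, Ptch1 and Gli2 ended without single control or estradiol arrays (0.057 to 0.13). With triclosan Gli1 lay at -0.41 ± 0.53 (adjusted p = 0.64, passing without Triclosan 2 at 0.01) and with zinc pyrithione at 0.70 ± 0.53 (0.61). Of 14 clock genes, 6 were called lower with estradiol, 1 higher and 7 did not pass, the core genes Bmal1, Clock, Per1, Per2, Cry1, Cry2 and Npas2. Of these core genes, Per2 (-0.87), Bmal1 (-0.66) and Cry2 (-0.56) changed call when certain single arrays were left out. Cry2 also passed with the filter on all 8 arrays (adjusted p = 0.041). The signs of Per1 and Cry2 turned with normexp. The nuclear receptor gene Nr1d1 (4.85-fold, -2.28 ± 0.17, adjusted p = 0.0014), its relative Nr1d2 (3.14-fold), Dbp (4.5-fold, -2.17 ± 0.25, adjusted p = 0.0022) and Tef (3.7-fold, -1.89 ± 0.18, adjusted p = 0.0018) fell with estradiol, and the repressor gene Bhlhe40 rose 6.66-fold (2.73 ± 0.50, adjusted p = 0.0074). These 5 calls held without any single array. Per3 (-0.74, adjusted p = 0.046) ended with 5 other settings (0.052 to 0.39), and Ciart was not well above background in either group. Ciart was at least 4.43-fold higher with zinc pyrithione (2.15 ± 0.14, adjusted p = 0.015) and at least 2.02-fold with triclosan (1.01 ± 0.14, 0.045). Both calls ended without most single arrays, with normexp and in the authors' table (0.13 to 0.35). That of triclosan also ended without a filter on dim probes (0.075). The other 13 clock genes did not pass with either chemical. With zinc pyrithione, Dbp (0.97 ± 0.25, 0.2) and Per2 (0.95 ± 0.32, 0.28) lay higher and Bmal1 (-1.86 ± 0.46, 0.2) and Npas2 (-1.06 ± 0.47, 0.37) lower. Nr1d1 lay at 0.82 ± 0.17 with zinc pyrithione and -0.98 ± 0.17 with triclosan (0.052, passing in some settings). Hours of dosing and collection were not used here.

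The first triclosan array lay farther along the estradiol response, at 0.559 of the way, than the second, at 0.234. Estradiol RNA mixed into a sample like the second would give genes raised and lowered by estradiol the same share, but the median share was 0.757 in 344 lowered and 0.179 in 668 raised genes, a gap of 0.578, which argues against mixing. On the first array 115 genes exceeded the controls, the estradiol arrays and the second triclosan array by over 2-fold, with Krt87, Tff1, cell division genes such as Birc5, Ccnb1 and Mki67, and muscle genes such as Acta1, Ckm, Acta2 and Cnn1 among them. The same count was 26 on the second triclosan array and 24 and 28 on the zinc pyrithione arrays, and, against only 3 other arrays, 65 and 53 on the control and 124 and 82 on the estradiol arrays. Lower brightness of the first array is argued against by a difference in position of 0.291 that remained in the 4374 brighter genes after quantile normalization, while other tissue in that sample and a difference in dose, in uptake or between animals stay open and were not tested.

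The list of endoplasmic reticulum chaperones was shifted upward in all treated groups at the preset correlation, which could come from the control arrays alone standing apart, but in none at an estimated correlation, and 0 of 14 genes passed for zinc pyrithione. For estradiol this is argued against as the whole cause, since the 14 chaperones were higher than with zinc pyrithione by a median log2 of 0.721 (quartiles 0.404 and 1.11). Zinc pyrithione against the controls gave 0.857 (quartiles 0.477 and 0.958), and here a rise with treatment and controls standing apart cannot be told apart. The sterol and NRF2 lists were also shifted upward in all treated groups at the preset correlation, so the same doubt applies to them. This doubt also covers the blood cell list, whose median was -0.38 with estradiol, -0.66 with triclosan and -0.45 with zinc pyrithione. That list passed with triclosan and zinc pyrithione and not with estradiol. The doubt was not tested for these lists or for the chaperones with triclosan. Among all genes, 2180 lay higher and 2381 lower on every treated array than on both control arrays. The same counts for the arrays outside a pair were 4804 and 4527 for estradiol, 618 and 803 for triclosan and 1534 and 994 for zinc pyrithione, so they do not show whether the controls stand apart.

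Orm1, an acute phase gene of the liver, was at log2 0.47 and 0.72 on the zinc pyrithione arrays, -7.70 and -7.23 on the control arrays, and -2.80 and -7.66 on the triclosan arrays. With the triclosan arrays left out it was at least 266-fold higher than in the controls (8.06 ± 0.19, adjusted p = 0.0018), while with all 8 arrays its adjusted p was 0.14. Liver RNA in these samples would also raise other liver genes, but 15 liver markers had a median log2 difference of -0.039 (quartiles -0.36 and 0.196), which argues against it. A response of the uterus or of single animals stays open and was not tested.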
